A study of Mus musculus with 15 samples.

How the data were processed

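Spleens came from female BALB/c mice, with an uninfected sample labelled naive mouse as week 0. The others were taken 4, 6, 12 and 16 weeks after percutaneous infection with 30 ± 2 cercariae of Schistosoma japonicum. Per the labels, erythrocytes were lysed in ACK buffer, cells passed a 70 μm strainer, and 10x Chromium 5′ RNA, TCR and BCR libraries were made. There was 1 library of each kind per week, 15 in all. The labels do not say how many mice gave the cells of a library.

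The deposited RNA values are counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger (version 4.0.0 per the file headers) on GRCm38/mm10, over 32285 genes. The deposited receptor files are counts of UMIs per assembled contig, also from Cell Ranger. No barcode held fewer than 500 UMIs, so barcodes with fewer appear to have been left out by the authors.

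Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were called with Scrublet in scanpy 1.11.5 separately in each library. Its own threshold called 551, 0, 1, 220 and 0 barcodes at weeks 0, 4, 6, 12 and 16, which is under 0.5% at weeks 4, 6 and 16, so the planned fixed rate was used. It removed the highest scores up to 0.8% per 1000 barcodes, and with them every barcode holding both a productive TCR chain and a productive BCR chain. This left 47811 of 53589 barcodes.

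All libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Immunoglobulin and T cell receptor segments, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes. Clusters of T and NK cells were clustered again by themselves, giving 53 clusters. Each was named after 19 marker lists by the class with the highest mean log2 ratio of CPM (counts scaled to a common total) to the other clusters, with 20 CPM added, where at least 3 markers were at least 2-fold higher, no other class had more markers among the 10 leading genes, and at least 1 own marker was among the 25 leading genes. Named classes are called "B-like" and so on, since the names rest on RNA alone. T clusters needed at least 200 CPM of Cd3e. They were named gamma-delta T-like above 100 CPM of Trdc, Treg-like where Foxp3 was at least 2-fold above the other T and NK clusters, CD8 T-like where Cd8a plus Cd8b1 exceeded 4 times Cd4, and CD4 T-like where Cd4 exceeded 2 times Cd8a plus Cd8b1. The thresholds on Cd3e, Trdc, Foxp3, the Cd4 to Cd8 ratio and the 25 leading genes were set after the clusters had been seen.

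Some clusters were kept out of a class on these rules. The share of kept barcodes in the cluster named gamma-delta T-like rather than CD8 T-like was 0.541%, 0.372%, 0.443%, 0.472% and 0.214% at weeks 0, 4, 6, 12 and 16. The share in a cluster named CD4 T-like rather than Treg-like was 0.522%, 1.20%, 0.507%, 1.90% and 1.07%. T cells of unassigned lineage, which include the cluster of dividing T cells, made up 1.30%, 1.55%, 0.516%, 0.618% and 0.475% and belong to no compared class. The 3 unnamed clusters held 0.466%, 0.562%, 0.244%, 0.094% and 0.107% in the largest of them, 0.047%, 0.131%, 0.190%, 0.199% and 0.153% in the next, and under 0.1% in the third.

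UMIs were summed per class and library and divided by the class total to give CPM. The 8 classes with at least 50 cells in every library were compared: CD4 T (with Treg), CD8 T, NK, B, plasma, neutrophil, monocyte and macrophage. Each infected library was compared with the week 0 library. With 1 library per week no test between groups was made and no p-value is given. Shares carry exact Clopper-Pearson intervals, ratios of shares Katz intervals, and CPM and their ratios exact Poisson or conditional binomial intervals, all at 95%. A share of 0 is given with the share that 3 counts would make and its exact upper limit. In ratios a count of 0 was set to 3 counts, so the fold is then a bound.

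The 26 gene lists were inhibitory receptors, exhaustion-associated transcription factors, naive T cell genes, T cell activation, Th1, Th2, Th17, Tfh, Treg, cytotoxic, type I interferon response, interferon-gamma response, proliferation, secretory and unfolded protein response, germinal centre, marginal zone, follicular and atypical B cell, antigen presentation, alternative macrophage activation, inflammatory myeloid, neutrophil granules and dissociation stress, with RNA of neutrophils, red cells and plasma cells found in other cells. Members needed 10 counts in 1 library, and at least 3 members had to be measured. A list is given as the median log2 CPM ratio to week 0, with a 95% interval from 1000 Poisson draws and its percentile among 10000 random lists matched on mean CPM (within 50 genes by rank on either side), as a description of these libraries. Mx1 was absent from the files. Some lists share genes: Tfh and inhibitory receptors share Pdcd1, Tfh and Th2 share Il4, Tfh and the exhaustion factors share Tox2, Treg and inhibitory receptors share Ctla4, Treg and activation share Il2ra, Tnfrsf4 and Tnfrsf9, Treg and Th2 share Il10, Th1 and activation share Cxcr3, and Th1 and cytotoxic share Ccl5 and Ifng.

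Genes were named by a rule. In each class, genes had to be at least 2-fold from week 0 the same way in all 4 infected libraries with at least 30 counts in the higher library, and were ranked by the smallest change. The first 8 higher and 5 lower genes were taken. For each week the 3 genes with at least 100 counts lying farthest above the other 4 libraries were added. Members of the lists could also be named. Immunoglobulin and receptor segments, mitochondrial, ribosomal and haemoglobin genes and unnamed gene models were left out. A few results are not reported here. The groups, comparisons, lists, rule and all alternatives but 2 were fixed before the data were examined. Leaving out the CD4 T-like cluster c37, the largest at week 6, and keeping only BCR barcodes of the RNA libraries were added afterwards.

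Shares of cells with a UMI were taken at full depth and after each cell was thinned to 1000 UMIs without replacement (seed 1). TCR clonotypes were defined by V gene, J gene and CDR3 nucleotide sequence of the productive alpha and beta chain with the most UMIs in the cell, and BCR clonotypes by those of the heavy chain. A clonotype of 2 or more cells was called expanded. Shares of expanded cells were averaged over 1000 draws of as many cells as the smallest library held.

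The ratio interval and the list statistic were tested on simulated data made from the CD4 T-like week 0 counts, with 200 changed genes (50 at each fold) among 10888. For weeks 4, 6, 12 and 16 against week 0, the interval held 95.59%, 96.24%, 95.89% and 96.01% of the 10688 unchanged genes within it. It excluded 1 for 100% of the genes set to 0.25-fold or 4-fold, for 100%, 96%, 98% and 94% of those at 0.5-fold, and for 100%, 100%, 100% and 98% of those at 2-fold. All 20 lists of 10 genes set to 2-fold reached percentile 100. Of the genes that the rule named, 8 of 8 higher and 5 of 5 lower ones had been changed in that direction. The simulated counts followed the Poisson model that the interval assumes, and the changed genes had at least 100 counts at week 0. This simulation therefore checks the computation only. It does not cover UMIs that come together in a few cells, or changed genes with few counts.

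Alternatives were scaling by TMM factors (edgeR 4.0.16 in R 4.3.3), means over cells, totals without immunoglobulin genes, thinned cells, week 4 as the baseline, other minimum counts for list members, CD4 T-like cells with a TCR beta chain and no BCR chain, CD4 T-like cells without Treg-like clusters, gating by Cd4 and Cd8 UMIs, resolution 2.0, each library clustered by itself, thinning before clustering, at least 500 genes and at most 5% mitochondrial UMIs, no doublet removal, classes taken from receptor chains, and other definitions of clonotypes and of the cells counted. TMM scaling moved the median log2 ratio of all genes by over 0.1 in B-like cells (0.12, 0.20 and 0.21 at weeks 4, 6 and 16), CD8 T-like cells (0.17 and 0.19 at weeks 6 and 16), monocyte-like cells (0.17 and 0.18 at weeks 6 and 16), neutrophil-like cells (0.22, 0.43, 0.25 and 0.48 at weeks 4, 6, 12 and 16), NK-like cells (0.15 at week 6) and plasma-like cells (0.41, 0.63 and 0.84 at weeks 6, 12 and 16). Coordinates are from GENCODE vM21 on GRCm38. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.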

Results

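Spleen cells of female BALB/c mice were profiled by 5′ single-cell RNA sequencing with paired T and B cell receptor sequencing over the course of infection with Schistosoma japonicum, a blood fluke whose eggs lodge in liver and gut. The first group was uninfected (week 0), and 4 groups were infected for 4, 6, 12 or 16 weeks. Each week had 1 RNA, 1 TCR and 1 BCR library, so there were no replicates, each week is also a library of its own, and all infected weeks share the same uninfected library. Values for weeks 0, 4, 6, 12 and 16, or for the 4 infected weeks, are given in that order. The RNA libraries held 12204, 11177, 12512, 10613 and 7083 barcodes with 42667255, 63500265, 72910513, 51886015 and 33472313 unique molecular identifiers (UMIs), and the median barcode held 2865, 3809, 3434, 3509 and 2812 UMIs. After filtering, 10728, 9956, 11052, 9544 and 6531 barcodes were kept. Intervals are at 95% and cover counting error only, not differences between mice. Those of summed UMIs also leave out that UMIs of a gene can come together in a few cells.

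Which cell types filled the spleen was the question of the first comparison. Neutrophil-like and plasma-like cells made up larger shares, and T-like cells smaller shares, of the infected libraries than of the uninfected one, most of all at weeks 6 and 16. Numbers of cells per spleen are not known here. Neutrophil-like cells made up 2.55% (2.26 to 2.86) of kept barcodes at week 0 and 3.80% (3.43 to 4.19), 24.1% (23.3 to 24.9), 7.36% (6.84 to 7.90) and 20.3% (19.3 to 21.3) afterwards, which is 1.49, 9.46, 2.89 and 7.98 times the week 0 share. Plasma-like cells, which secrete antibody, made up 0.513% (0.386 to 0.667), then 1.74% (1.49 to 2.01), 3.11% (2.80 to 3.45), 1.46% (1.23 to 1.72) and 4.20% (3.72 to 4.71). CD4 T-like cells with Treg-like cells were 24.5% (23.7 to 25.3) at week 0 and 16.0% (15.3 to 16.7), 10.6% (10.1 to 11.2), 17.3% (16.5 to 18.1) and 13.2% (12.4 to 14.1) afterwards. CD8 T-like cells were 13.02%, 10.5%, 6.14%, 12.8% and 7.76%, and NK-like cells 3.81%, 4.50%, 1.19%, 2.23% and 1.38%. With each library clustered by itself, 0 of 6531 barcodes at week 16 were named NK-like, so that value depends on clustering the libraries together.

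Among rarer cells, progenitor-like and erythroid-like cells had their largest shares at weeks 6 and 16. Progenitor-like cells numbered 2, 10, 157, 19 and 58, or 0.019%, 0.1%, 1.42%, 0.199% and 0.888% of kept barcodes, and erythroid-like cells were 1.02%, 1.17%, 3.29%, 0.765% and 2.51%, although red cells had been lysed. Monocyte-like cells were 1.01%, 1.39%, 4.28%, 1.08% and 2.30%. Basophil-like or mast-like cells, carriers of IgE on their surface, numbered 10, 33, 73, 41 and 25, which is 3.56, 7.09, 4.61 and 4.11 times the week 0 share. B-like cells were the largest class in every library, at 45.4%, 52.1%, 39.7%, 50.7% and 40.7%. Macrophage-like cells were 2.70%, 2.37%, 1.28%, 1.62% and 1.81%, but 1.27%, 1.05%, 0.751%, 0.593% and 0.808% with at least 500 genes and at most 5% mitochondrial UMIs, and 1.29%, 1.07%, 0.985%, 0.878% and 0.784% with cells thinned before clustering. Conventional dendritic-like cells stayed between 1.88% and 2.71%. No cluster met the rule for eosinophils or stromal cells.

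**Figure D1:**
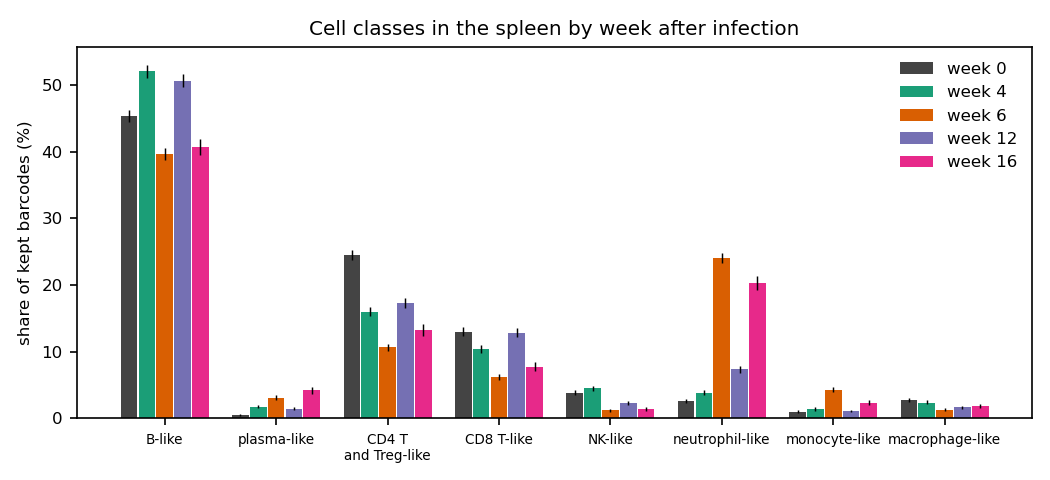
Share of kept barcodes (percent, linear axis from 0) of 8 cell classes, with 1 bar per week and class and error bars for the exact 95% interval of counting error. Neutrophil-like cells stand at 24.1% and 20.3% at weeks 6 and 16 against 2.55% at week 0.

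The shares add to a whole, so a higher share of neutrophil-like cells lowers the others in the same library. The combined CD4 T-like and Treg-like share moved with the way of classing cells but stayed below week 0 in each of them.

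CD4 T cells are the subject named in the series title, which speaks of their exhaustion, a state in which long-stimulated T cells carry inhibitory receptors. In the infected libraries CD4 T-like cells held more RNA of inhibitory receptors and of T follicular helper (Tfh) and Th2 genes, and less of genes of naive cells. Pdcd1, the receptor PD-1, was 4.20-fold (3.46 to 5.12), 5.05-fold (4.08 to 6.28), 5.85-fold (4.85 to 7.09) and 3.71-fold (2.91 to 4.72) its week 0 level of 16.5 CPM (counts scaled to a common class total). Il4, the signature Th2 cytokine, which Tfh cells also make, was 10.2-fold (7.81 to 13.6), 12.4-fold (9.37 to 16.8), 10.9-fold (8.34 to 14.5) and 13.3-fold higher. These values come from 2629, 1594, 1176, 1649 and 865 cells with median depths of 3057, 3313.5, 2181, 3285 and 2384 UMIs.

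Of 9 measured inhibitory receptors, 5, 6, 5 and 5 were at least 2-fold higher and none 2-fold lower, and the list median log2 ratio was 1.34 (1.06 to 1.51), 1.17 (0.96 to 1.48), 1.22 (1.07 to 1.46) and 1.43 (1.21 to 1.59), at percentile 100 of matched random lists in each week. Lag3, a receptor for MHC class II, was 5.13-fold (4.29 to 6.17), 3.19-fold (2.55 to 4.00), 4.86-fold (4.06 to 5.86) and 3.08-fold (2.42 to 3.92) higher. Tigit, which binds CD155, was 4.44-fold (3.71 to 5.35), 4.61-fold (3.75 to 5.67), 4.89-fold (4.08 to 5.88) and 6.28-fold (5.13 to 7.70) higher. Ctla4, which competes with CD28 for its ligands, was 2.72, 1.80, 2.32 and 2.69 times its week 0 level, and Cd200 2.53, 2.10, 3.30 and 3.09 times. Havcr2, which encodes TIM-3, had only 0, 8, 1, 6 and 0 counts, and Vsir stayed between 0.902-fold and 1.20-fold. Pdcd1 (ENSMUSG00000026285) lies on chromosome 1 at 94038305 to 94052553 of GRCm38, Lag3 (ENSMUSG00000030124) on chromosome 6 at 124904361 to 124911705, Tigit (ENSMUSG00000071552) on chromosome 16 at 43648867 to 43664146, and Il4 (ENSMUSG00000000869) on chromosome 11 at 53602982 to 53618669.

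As a share of cells, Pdcd1 UMIs were seen in 3.31%, 12.3%, 11.2%, 15.3% and 9.48% of CD4 T-like cells and in 0.082%, 0.251%, 0.023%, 0.062% and 0.038% of B-like cells, whose median depths were 2578, 3684, 2883, 3182 and 2479 UMIs. With each cell thinned to 1000 UMIs the CD4 T-like shares were 1.48% (1.05 to 2.03), 5.12% (4.07 to 6.34), 7.23% (5.78 to 8.92), 7.63% (6.38 to 9.03) and 6.22% (4.68 to 8.08), and the B-like shares 0.022%, 0.041%, 0%, 0.021% and 0%, where 3 counts would be 0.073% and 0.12% and the exact upper limits are 0.089% and 0.148%. Thinning left out 67, 50, 70, 36 and 29 CD4 T-like cells and 221, 300, 253, 164 and 169 B-like cells. Tigit UMIs were in 3.01%, 13.7%, 11.0%, 12.9% and 15.03% of CD4 T-like cells (thinned 1.25%, 5.76%, 5.24%, 6.01% and 9.93%), against at most 0.308% of B-like cells. Lag3 UMIs were in 2.63%, 11.7%, 8.16%, 13.2% and 8.09% (thinned 1.29%, 5.83%, 4.61%, 6.26% and 4.43%), against at most 0.424% of B-like cells.

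**Figure D2:**
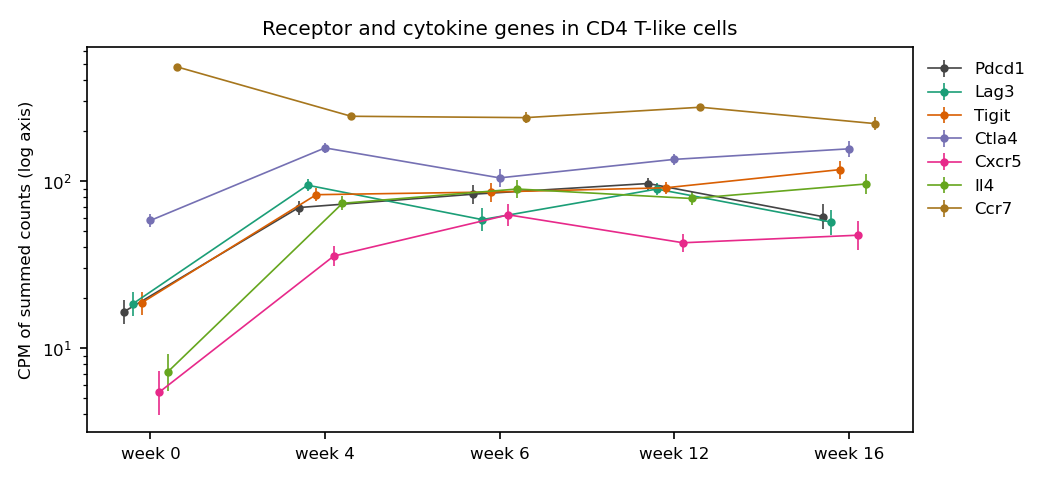
Level of 7 genes in CD4 T-like cells (CPM of summed counts, log axis) by week, with points for the 5 libraries joined by lines and error bars for the exact 95% Poisson interval. Pdcd1 stands at 16.5 CPM at week 0 and between 61.1 and 96.5 CPM afterwards, while Ccr7 lies at 0.456-fold to 0.572-fold of week 0.

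Transcription factors linked to exhaustion were higher too, with 8, 6, 7 and 5 of 10 at least 2-fold higher, 0, 1, 0 and 0 at least 2-fold lower and list medians of 1.47 (1.21 to 1.77), 1.55 (1.17 to 1.76), 1.61 (1.31 to 2.06) and 0.95 (0.68 to 1.28). Maf, which also drives Il4 and Il21 expression, was 4.28-fold (3.82 to 4.81), 5.11-fold (4.51 to 5.81), 4.66-fold (4.16 to 5.23) and 4.85-fold (4.24 to 5.55) higher. Irf4, needed for effector T cell growth, was 4.39, 4.46, 4.63 and 2.65 times week 0, and Prdm1, which encodes Blimp-1, 3.23, 3.48, 3.63 and 2.65 times. Tox, the factor most tied to lasting exhaustion of CD8 T cells, was 1.44, 1.58, 1.38 and 1.07 times week 0 (0.916 to 1.26 at week 16). Eomes stood at 3.59, 3.26, 5.79 and 1.84 times.

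Tfh genes, of cells that help B cells in germinal centres, had list medians of 1.84 (1.68 to 2.16), 2.40 (2.16 to 2.80), 2.39 (2.13 to 2.64) and 2.06 (1.86 to 2.44), with 6, 7, 6 and 8 of 8 members at least 2-fold higher. Cxcr5, which guides cells into follicles, was 6.54-fold (4.74 to 9.21), 11.6-fold (8.31 to 16.4), 7.86-fold (5.72 to 11.0) and 8.73-fold (6.12 to 12.6) higher. Il21, a cytokine for B cells, was 6.90, 4.82, 4.21 and 3.41 times week 0, Bcl6, the master regulator of Tfh cells, 2.90, 5.51, 5.45 and 4.46 times, and Tox2 3.04, 7.34, 5.04 and 6.01 times. Th2 genes had medians of 2.10 (1.57 to 2.70), 1.62 (0.62 to 2.36), 1.50 (1.23 to 2.50) and 1.51 (0.49 to 2.51), with 5, 4, 4 and 4 of 8, 7, 8 and 7 members at least 2-fold higher and 1, 0, 1 and 1 at least 2-fold lower. Il13, which drives fibrosis around eggs, had 0 counts at week 0 and 179, 2, 4 and 0 afterwards. With 3 counts set for week 0, the level of week 4 was 85.1-fold higher. Its UMIs were then in only 0.439% of CD4 T-like cells (thinned 0.259%, 0.071 to 0.662, and B-like cells 0.058%). The fold thus rests on few cells and is no lower bound where cells are counted. Il10, an anti-inflammatory cytokine, was 17.8-fold (6.55 to 68.0), 3.07-fold (0.573 to 16.5), 10.7-fold (3.74 to 41.7) and 2.84-fold (0.416 to 16.8) of week 0, from 4, 50, 4, 29 and 3 counts. Il1rl1, the IL-33 receptor, was 5.93, 3.78, 6.11 and 6.12 times week 0. Gata3, the Th2 master regulator, was 1.65, 1.37, 1.67 and 1.50 times.

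**Figure D3:**
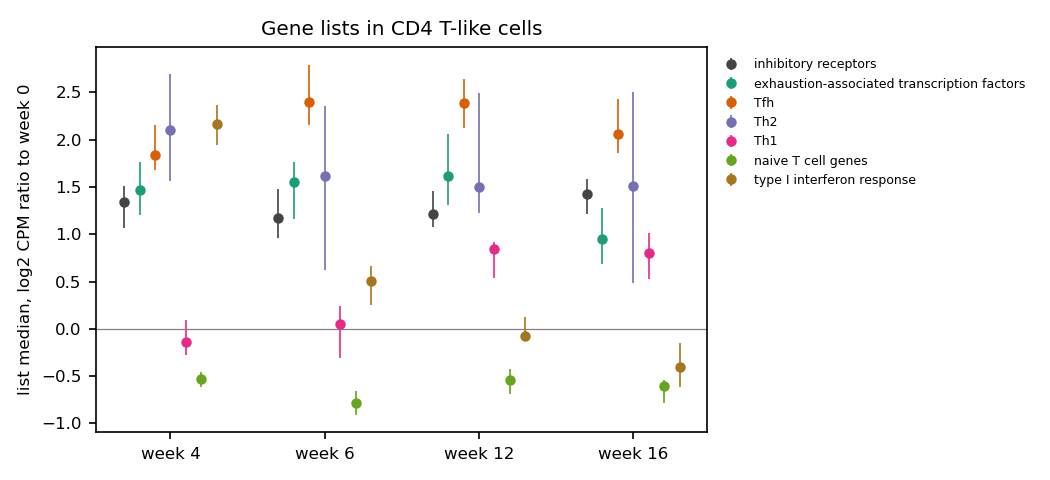
Median log2 CPM ratio to week 0 of 7 gene lists in CD4 T-like cells at weeks 4, 6, 12 and 16, with error bars for the 95% interval from Poisson draws. The Tfh list lies between 1.84 and 2.40, and the list of naive T cell genes between −0.78 and −0.53.

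Treg genes had medians of 1.13, 0.88, 0.74 and 0.78, with Foxp3, the Treg master regulator, at 1.41, 1.29, 1.21 and 1.12 times week 0 and Ikzf2 at 2.34, 2.07, 1.66 and 1.48 times, while Treg-like cells were 299 of 2629, 326 of 1594, 178 of 1176, 239 of 1649 and 125 of 865 cells of the class. Th1 genes had medians of −0.14, 0.05, 0.85 and 0.81, and Cxcr3, a receptor of Th1 cells, was 0.937, 1.07, 1.92 and 2.01 times week 0. Activation genes had medians of 0.45, 0.28, 0.94 and 0.82, led by Icos at 2.99, 1.89, 2.76 and 1.962 times and Tnfrsf4, which encodes OX40, at 3.70, 2.49, 3.57 and 3.38 times. Cytotoxic genes had medians of 0.51, 0.37, 0.92 and 0.93, and Gzmb, a granzyme, was 16.0-fold (9.56 to 28.5) higher at week 4. Proliferation genes had medians of 1.37, 0.43, 0.48 and 0.28, with 8, 2, 3 and 2 members at least 2-fold higher. The cluster of dividing T cells, with 32, 77, 33, 18 and 14 cells, had no assigned lineage and is not in these sums. The medians therefore leave out most clearly dividing T cells. For Th17 genes too few members were measured, and Il17a, Il17f and Il22 had 0 counts.

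Naive T cell genes lay below 0 in all 4 infected libraries, with medians of −0.53 (−0.61 to −0.45), −0.78 (−0.91 to −0.66), −0.54 (−0.69 to −0.43) and −0.60 (−0.78 to −0.54). Ccr7, which brings T cells into lymphoid tissue, was 0.505, 0.496, 0.572 and 0.456 times week 0, and Lef1 0.572, 0.496, 0.615 and 0.445 times. Tcf7 was 0.912, 1.24, 0.925 and 1.09 times. Interferon genes peaked at week 4, when 10 of 11 type I interferon response genes were at least 2-fold higher and the list medians ran 2.17 (1.94 to 2.37), 0.50, −0.07 and −0.40. Isg15 was 6.05-fold (5.53 to 6.62) and Ifit3 8.52-fold (6.52 to 11.3) higher at week 4, both antiviral effectors. The interferon-gamma response medians were 0.69, −0.03, 0.36 and −0.20.

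By the rule for named genes, Gfra4, a receptor subunit for persephin, was 10.2-fold (6.92 to 15.5), 21.7-fold (14.8 to 33.0), 20.7-fold (14.3 to 31.1) and 20.1-fold (13.5 to 30.7) higher. Csf1, a growth factor of macrophages, was 12.5, 7.54, 8.47 and 6.31 times week 0, and Ifitm2, an antiviral membrane protein, 12.2, 7.87, 11.2 and 12.0 times. Gpm6b, Ces2c and Cebpa, the last a myeloid transcription factor, were at least 5.92-fold, 7.13-fold and 6.06-fold higher in every infected library. Lower in all 4 were Zbtb16, which encodes PLZF of innate-like T cells, at 0.179, 0.274, 0.154 and 0.139 times, Klrd1, which encodes CD94, at 0.265, 0.124, 0.368 and 0.244 times, and Lypd6b. Adh1 and the haem synthesis gene Alas2 were lower as well, the latter with 31 counts at week 0 and 0 later. Week 4 was also marked by Ifit3b (9.78-fold) and Oas2 (5.40-fold), week 12 by Serpina3i (6.08-fold), Ptger2, a prostaglandin receptor (3.51-fold), and Irf8 (1.93-fold), and week 16 by Dusp1 (2.51-fold), Zfp36l2 (1.77-fold) and Hypk (1.64-fold). Tet1 was highest at week 0.

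The subclusters behind these sums differed by week: the cluster that held 71.8% of CD4 T-like cells without Treg-like cells at week 0 held 35.4%, 11.0%, 36.3% and 18.9% later, and the one led by Gfra4, Maf, Pdcd1 and Il4 held 1.33%, 13.1%, 24.6%, 20.9% and 22.8%. The largest cluster at week 6, c37, held 5.06%, 5.36%, 37.7%, 3.12% and 14.6%, was led by Igfbp4, Cd3e and Lef1, and had a TCR beta chain in 53.2% of its cells. Genes of dissociation stress had medians of −0.66, −0.49, −0.51 and 0.10 in CD4 T-like cells. Neutrophil RNA in CD4 T-like cells had list medians of 0.35, 3.97, 1.28 and 3.002 (Lcn2, Lyz2 and Ngp, the genes named for week 6, are neutrophil or myeloid genes), plasma cell RNA 1.59, 2.62, 1.14 and 2.17, and red cell RNA −5.14, −2.66, −6.13 and −4.54.

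Whether CD8 T and NK cells took on the same genes was asked next. In CD8 T-like cells the inhibitory receptor list medians were 0.35 (0.05 to 0.73), 0.12 (−0.54 to 0.48), 0.08 (−0.28 to 0.41) and 0.71 (−0.15 to 0.95), and that of week 12 was 0.51 with cells thinned to 1000 UMIs. Pdcd1 was 1.03-fold (0.621 to 1.72), 0.499-fold (0.187 to 1.14), 0.782-fold (0.460 to 1.32) and 0.362-fold (0.0932 to 1.01) of week 0, from 34, 33, 7, 29 and 4 counts. Tigit was higher, at 2.93, 1.65, 3.28 and 3.62 times, as was Lag3 at weeks 4 and 12, at 2.59 and 2.04 times. The difference between CD4 and CD8 T-like cells was not tested.

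Among the genes named by the rule in CD8 T-like cells, Gzmm, a granzyme, was 4.10-fold (3.37 to 5.01), 4.51-fold (3.63 to 5.63), 8.26-fold (6.88 to 9.98) and 5.27-fold (4.22 to 6.59) higher, and Il2rb, a subunit of the IL-2 and IL-15 receptors, 2.74, 3.32, 3.07 and 2.77 times. Cish, an inhibitor of cytokine signalling, stood at 4.57, 5.15, 2.79 and 3.97 times and Rgs1, which damps chemokine signals, at 3.86, 3.40, 3.56 and 5.56 times. Tspan9, N4bp1 and Rnf19b were at least 5.48-fold, 3.07-fold and 2.70-fold higher in each infected library. Cytotoxic list medians were 0.30, −0.02, 0.44 (0.35 to 0.57) and 0.75 (0.35 to 1.03), with Cst7 at 2.31, 1.56, 2.59 and 2.46 times week 0, while Klrg1, a marker of short-lived effector cells, was 0.548, 0.139, 0.550 and 0.527 times. Itgae, which encodes CD103, was 0.316, 0.103, 0.202 and 0.130 times week 0, Sox4 0.335, 0.360, 0.210 and 0.105 times, and Rarg, Car2 and Tubb2a were lower too. Naive gene medians were −0.16, −0.13, −0.55 and −0.36, and that of week 6 was 0.037 under scaling by trimmed means. Week 4 stood out by the interferon genes Rsad2 (16.1-fold), Oas2 (15.4-fold) and Ifit3b (13.9-fold), with a type I interferon list median of 2.47 (2.32 to 2.62) and all 11 members at least 2-fold higher. Week 12 stood out by the chemokines Ccl3 (4.46-fold) and Ccl4 (3.82-fold), week 16 by Hopx (3.62-fold), S100a6 (3.21-fold) and Crip1 (2.21-fold), and week 6 by Bcl2l11, which encodes the death factor BIM (1.63-fold). The clusters behind these sums differed by week: the largest at week 0 held 76.0%, 45.1%, 12.4%, 33.1% and 16.6% of CD8 T-like cells, another led by Gzmm and Eomes 7.23%, 20.9%, 25.2%, 44.4% and 31.2%, and a further one 4.01%, 4.03%, 41.7%, 4.98% and 25.8%. Gzmm (ENSMUSG00000054206) lies on chromosome 10 at 79689020 to 79695261.

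NK-like cells, at 409, 448, 131, 213 and 90 cells, gained Tigit (9.92-fold, 6.40 to 16.2, at week 4, then 7.26, 3.85 and 5.71 times week 0) and Lag3 (8.90-fold, 4.72 to 18.9, then 5.45, 4.24 and 4.80 times). Pim2, a kinase of cell survival, was 4.79, 4.77, 6.62 and 2.12 times week 0, and Kbtbd11, Thy1 and H2-Q6 were at least 2.15-fold, 2.02-fold and 2.17-fold higher. Elovl7 was 0.290, 0.314, 0.331 and 0.384 times, and Nebl, Selenom, St5 and Hist1h2ak were lower too. Their inhibitory receptor medians were 0.88, 0.72, 0.85 and 0.34, and their cytotoxic medians −0.25, −0.20, 0.13 and −0.15. At week 4 Ifi27l2a was 11.2-fold and Ly6a 10.8-fold higher, both interferon-induced, and at week 12 the MHC class II genes H2-Aa (3.24-fold), H2-Eb1 (3.67-fold) and Cd74 (1.99-fold) were highest. H2-Aa, H2-Eb1 and Cd74 are also leading genes of B-like clusters, and RNA carried over from B-like cells was not tested here. Neutrophil RNA reached a list median of 3.62 in CD8 T-like cells at week 6.

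The B cell comparison asked how the humoral response differed by week. Germinal centre genes were higher in B-like cells of all 4 infected libraries, with list medians of 2.55 (2.41 to 2.73), 2.38 (2.22 to 2.54), 2.25 (2.10 to 2.41) and 1.56 (1.42 to 1.79), percentile 100 each time, and 7 of 8 members at least 2-fold higher. Mef2b, a transcription factor upstream of Bcl6, was 8.37, 5.92, 7.42 and 4.41 times week 0, and Rgs13, which damps chemokine signals in germinal centres, 11.2, 9.16, 10.6 and 6.62 times. S1pr2, which holds cells in the germinal centre, was 5.20, 4.996, 3.83 and 2.95 times, Gcsam 8.77, 7.19, 6.98 and 4.25 times, and Fas, a death receptor, 2.82, 2.67, 3.17 and 2.69 times. Bcl6 itself was 1.16, 1.25, 1.44 and 1.06 times. Mef2b (ENSMUSG00000079033) lies on chromosome 8 at 70139711 to 70167488 and Rgs13 (ENSMUSG00000051079) on chromosome 1 at 144138654 to 144177372.

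Dividing cells went along with this. Proliferation list medians were 2.26, 2.12, 1.71 and 1.26, with 13, 13, 11 and 7 of 13 members at least 2-fold higher, among them Mki67 at 5.93, 4.93, 3.78 and 1.93 times and Top2a, a topoisomerase, at 4.79, 4.06, 3.43 and 1.63 times. Follicular B cell genes were lower, with medians of −1.10 (−1.13 to −1.07), −1.01 (−1.06 to −0.96), −0.46 and −0.49, Fcer2a, which encodes CD23, at 0.338, 0.406, 0.780 and 0.416 times and Ccr7 at 0.345, 0.249, 0.493 and 0.552 times. Marginal zone genes had medians of −0.73, −0.08, −0.67 and −0.23, of which that of week 6 turned to 0.12 under scaling by trimmed means, and Cd9 was 0.577, 0.469, 0.350 and 0.586 times week 0. Atypical B cell genes had medians of −0.26, −0.53, −0.09 and −0.50, although Itgax, which encodes CD11c, was 2.29-fold higher at week 16. Antigen presentation genes had medians of −0.23, −0.31, 0.18 and 0.16, with Cd80, a costimulator, 2.92-fold higher at week 16. Ighg1, the IgG1 constant gene, was 70.1-fold (50.3 to 101), 137-fold (98.3 to 197), 92.9-fold and 90.1-fold above 2.31 CPM. Plasma cell RNA in B-like cells had list medians of 0.46, 0.51, 0.28 and 0.25. That list holds Ighg1 itself, and its member Mzb1 is also a leading gene of B-like clusters. Its medians therefore cannot tell how much of the Ighg1 gain was RNA carried over from plasma-like cells. The same list was higher in CD4 T-like cells of all infected libraries, as given earlier.

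Further genes named by the rule in B-like cells were Parm1 (12.1, 27.6, 34.3 and 35.8 times week 0), Fscn1, an actin-bundling protein (12.2, 14.7, 20.8 and 16.2 times), Lifr, a cytokine receptor (14.1, 17.5, 22.1 and 18.7 times), Atp11a (14.9, 22.0, 16.4 and 15.6 times), H1fx, a linker histone (17.6, 11.0, 7.46 and 8.94 times), and Olfr1388. Gnaz had 1 count at week 0 and was 109-fold (19.4 to 4331) higher at week 4, and Bmpr1a had 2 and was 20.4-fold (5.46 to 171) higher. Wfdc21 was 0.194, 0.179, 0.127 and 0.139 times week 0, Adm, which encodes a vasodilator peptide, 0.210, 0.0962, 0.188 and 0.158 times, and Xlr3b, Islr2 and AF067061 were lower at few counts. Week 4 stood out by interferon genes, with a type I list median of 2.92 (2.76 to 3.09) against 0.75, −0.15 and −0.48 later, Ifi44 12.5-fold, Isg15 7.59-fold (6.79 to 8.50) and Rsad2 22.1-fold (9.998 to 60.7) higher. Week 12 stood out by Ccl22, a chemokine for CCR4-bearing T cells (118-fold, 20.8 to 4672, from 1 count at week 0), Emp2 (at least 99.3-fold) and Igf2bp3 (4.55-fold), week 16 by Prkcz (4.02-fold), Hs3st1 (3.58-fold) and Snhg18 (2.19-fold), and week 6 by Mfap1b (4.97-fold).

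A cluster led by germinal centre genes held 1.58%, 15.3%, 15.4%, 9.26% and 8.27% of B-like cells, and the largest cluster held 43.4%, 20.5%, 21.6%, 44.9% and 31.5%. A cluster with Ly6d and Vpreb3 among its leading genes held 24.1%, 10.8%, 0.34%, 4.98% and 2.59%, and another with Ly6a 0.55%, 14.9%, 2.90%, 1.36% and 0.45%. Genes of dissociation stress had medians of −1.54, −1.53, −1.26 and −0.76 in B-like cells. Neutrophil RNA in B-like cells had list medians of 0.02, 3.19, 1.14 and 2.75, and Elane and Mpo, named for week 6, are neutrophil genes.

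Plasma-like cells, at 55, 173, 344, 139 and 274 cells, held another mix of antibody classes in the infected libraries. Ighg1 was 19.2-fold (17.6 to 20.9), 24.9-fold (22.8 to 27.1), 27.2-fold and 35.8-fold (32.9 to 39.1) higher, and Ighe, the IgE constant gene, 6.00-fold (3.21 to 12.7), 112-fold (60.6 to 233), 68.5-fold (37.1 to 143) and 76.2-fold (41.4 to 159) higher, from 10 counts at week 0. By their receptor sequences, only 1 of 54 plasma-like cells at week 0 had an IgG1 heavy chain. IgE was in 0 of 54 at week 0 and in 1 of 169 at week 4. The week 0 levels and the week 4 Ighe fold thus rest on very few cells, which these intervals do not cover. Igha was 1.44, 1.65, 0.499 and 0.884 times week 0. Proliferation genes had medians of 0.18, −0.40, −1.49 (−1.73 to −0.95) and −1.76 (−2.10 to −1.49), with 9 and 11 of 13 at least 2-fold lower at weeks 12 and 16, where Mki67 was 0.258 and 0.181 times week 0. Under scaling by trimmed means the medians of weeks 6, 12 and 16 were 0.011, −0.86 and −0.92, and with cells thinned to 1000 UMIs those of weeks 4, 6 and 16 were 1.15, 0.93 and −0.33. Slpi, a protease inhibitor and a gene that leads this cluster, was 5.74, 8.97, 6.01 and 18.9 times week 0, Zbp1, a nucleic acid sensor, 4.04, 3.51, 2.11 and 3.71 times, and Mt1, a metallothionein with 3 counts at week 0, 5.78, 8.30, 12.7 and 29.0 times. S100a10 was 0.205, 0.0935, 0.0629 and 0.0543 times, Ahnak, a large scaffold protein, 0.158, 0.0677, 0.0312 and 0.0430 times, and Crip2, Dusp1 and Ifitm1 were lower too. Type I interferon medians were 1.73, −0.17, −0.72 and −1.17, and those of weeks 6, 12 and 16 were 0.16, −0.09 and −0.33 under scaling by trimmed means and 0.27, −1.69 and −1.80 with thinned cells. Secretory genes had medians of 0.48, 0.06, −0.48 and −0.58, and the same scaling took those of weeks 6, 12 and 16 to 0.47, 0.14 and 0.27, and totals without immunoglobulin genes took them to 0.08, −0.08 and −0.27.

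How myeloid cells differed was the next question. Summed over the class, neutrophil-like cells of the infected libraries held less RNA of inflammatory genes. Il1b, a cytokine of the inflammasome, stood at 2526 CPM at week 0 and was 0.238-fold (0.221 to 0.256), 0.0602-fold, 0.118-fold and 0.163-fold of that later, Nlrp3, the inflammasome sensor, 0.308, 0.0905, 0.139 and 0.190 times, and Ptgs2, which makes prostaglandins, 0.0756, 0.00922, 0.0847 and 0.108 times. The inflammatory list medians were −2.07, −1.43, −2.84 and −2.40. Genes of dissociation stress were also lower in these cells, with medians of −1.86, −2.56, −2.27 and −1.14, as was red cell RNA, at −8.32, −7.26, −9.65 and −7.71, so handling of the week 0 sample is not separated from infection here. Elane, neutrophil elastase, was 3.64-fold (2.09 to 6.86), 19.3-fold (11.5 to 35.3), 10.5-fold (6.21 to 19.2) and 10.04-fold (5.96 to 18.4) higher, Prtn3 1.51, 7.10, 3.71 and 3.35 times and Mpo, myeloperoxidase, 1.45, 7.31, 5.03 and 4.42 times. Camp, Ngp, Ltf and Mmp9 of the granule list also served to name the class, and the list medians were 0.48, 0.68, 0.68 and 0.38. Prok2, a chemokine-like peptide, was 6.59, 34.7, 2.63 and 9.51 times week 0, and Gpr27, Ctla2a, Tdg, Acbd3, Brf1 and Fam241a were named as well, with few counts at week 0. Lower genes included Nr4a1, Cd244a, Tnni2 and Fgl2, the last at 0.228, 0.0466, 0.134 and 0.0961 times. Week 4 again had interferon genes, Oasl2 (13.9-fold), Usp18 (4.32-fold) and Ifit3 (4.27-fold), and the type I list ran 1.27, −1.21, −1.13 and −1.79. Cxcl2 and Osm were highest at week 16, at 2.87-fold and 1.61-fold, and Lipg at week 6. Antigen presentation genes had medians of −0.33, −1.70, −1.47 and −1.35.

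These sums came from 273, 378, 2660, 702 and 1326 cells with median depths of 1335, 2627, 4904, 5484.5 and 4779 UMIs, and the cluster with 74.7% of them at week 0 held 49.5%, 15.8%, 29.2% and 30.3% later. It alone among neutrophil-like clusters had Il1b among its leading genes, while the others had Camp, Ngp and Ltf. A different mix of neutrophil-like cells is therefore not separated from a change within cells.

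Monocyte-like cells, at 108, 138, 473, 103 and 150 cells, held more RNA of dividing cells. Proliferation medians were 1.31, 2.23, 1.64 and 2.03, with 10, 13, 12 and 12 of 13 members at least 2-fold higher, Kif11, a spindle motor, at 5.37, 9.97, 7.37 and 6.79 times week 0 and Rrm2, which makes deoxyribonucleotides, at 6.39, 19.2, 9.02 and 14.9 times. Prtn3 was 15.2, 38.7, 17.6 and 28.4 times week 0, S100a8 7.88, 23.1, 11.9 and 32.4 times, and Lcn2, with 0 counts at week 0, at least 10.2-fold, 58.4-fold, 9.57-fold and 45.8-fold higher. Elane, Tyms and Wfdc21 were named too. Neutrophil RNA in monocyte-like cells had list medians of 1.04, 3.08, 0.88 and 2.57, and S100a8, Lcn2, Wfdc21 and Chil3 also lead neutrophil-like clusters. Genes named as lower were Cx3cr1 at 0.119, 0.237, 0.311 and 0.233 times and Cd300e at 0.251, 0.162, 0.239 and 0.0636 times, together with the lipid handlers Fabp4 and Cd36 and with Slc46a3, and the cluster with Ace and Fcgr4 among its leading genes held 35.2%, 13.04%, 16.9%, 16.5% and 5.33% of monocyte-like cells. Alternative activation, known from macrophages in worm infection, had list medians of 0.70, 0.25, −0.29 and 0.29 with 1 of 6, 6, 4 and 4 members at least 2-fold higher each week. Chil3, which encodes Ym1, was 1.93-fold (1.44 to 2.62), 6.11-fold (4.71 to 8.08), 4.37-fold (3.30 to 5.87) and 9.46-fold (7.27 to 12.5) higher, whereas Arg1 had 1 count in all libraries together and Retnla 0. Interferon-gamma response medians were 1.22, −0.37, 0.95 and −0.25, of which those of weeks 6 and 16 turned to 0.35 and 0.30 with cells thinned to 1000 UMIs, with Cxcl9 4.71-fold (2.40 to 10.3) higher at week 12 and Gbp2 at 4.24, 1.07, 4.42 and 1.27 times. Week 4 stood out by Socs1 (17.7-fold from 3 counts), Slfn4 (8.68-fold) and Spon1 (8.27-fold).

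Macrophage-like cells, at 290, 236, 141, 155 and 118 cells with median depths of 848, 797.5, 1005, 767 and 761 UMIs, had interferon-gamma response medians of 1.52 (0.84 to 1.91), 0.05, 1.34 (0.59 to 1.97) and −0.04. Cxcl9, a chemokine for activated T cells, was 6.57, 3.88, 11.1 and 0.375 times week 0 and Gbp2 4.34, 0.905, 4.11 and 1.31 times. Irf7 was 9.43-fold (6.87 to 13.2) higher at week 4. Cd63, a lysosomal membrane protein, was 3.64, 5.79, 6.67 and 3.68 times week 0, Lyz1, a lysozyme, 39.1, 109.6, 44.0 and 25.6 times, Serpina3g 5.84, 4.24, 3.25 and 2.01 times and Wfdc17 5.41, 10.3, 8.34 and 16.2 times. The cluster led by Lyz2 and Lyz1 held 9.66%, 19.9%, 26.2%, 33.6% and 12.7% of macrophage-like cells. Mrc1, the mannose receptor, was 0.942, 0.932, 0.931 and 1.26 times, and the alternative activation medians were 0.11, −0.27, −0.05 and 0.30 over 4 members. Trf, which encodes transferrin, was 0.471, 0.439, 0.457 and 0.519 times week 0. The MHC class II gene H2-Ab1 was 2.91-fold higher at week 16, and Ctsd, a lysosomal protease, 2.17-fold at week 6. Neutrophil RNA reached a median of 2.90 there at week 6.

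Whether T cell clones grew during infection was asked of the TCR libraries. Expanded clonotypes, seen in 2 or more cells, held a small share of T cells in every library. They held 2.38% (1.90 to 2.95), 4.41% (3.58 to 5.36), 5.02% (3.71 to 6.62), 6.68% (5.73 to 7.73) and 4.70% (3.39 to 6.32) of 3401, 2155, 936, 2500 and 873 cells with paired chains. Drawn to 873 cells each, the shares were 0.707%, 2.02%, 4.82%, 2.77% and 4.70%, and the inverse Simpson index, which counts equally common clonotypes, was 867, 854, 806, 845 and 819. With T-like cells of the RNA libraries alone, drawn to 716 cells, the shares of weeks 4 and 6 were 1.18% and 3.07%. The largest clonotypes held 3, 4, 5, 7 and 4 cells. Among CD4 T-like and Treg-like cells 2.44%, 4.00%, 5.09%, 7.82% and 4.49% were in expanded clonotypes, and among CD8 T-like cells 1.65%, 2.38%, 1.32%, 3.56% and 5.0%. These class shares, of 1843, 1024, 432, 1215 and 468 and of 969, 673, 228, 898 and 260 cells, were not drawn to a common number. Their order by week may also follow the number of cells. The TCR beta chain was found in 89.7%, 84.3%, 62.4%, 90.3% and 77.3% of CD4 T-like cells, so fewer clones could be seen at weeks 6 and 16. Only 1 clonotype with both chains was shared by any libraries, those of weeks 4 and 12.

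How expanded cells differed from single ones was then compared inside each library, where the week is the same. In CD4 T-like cells of expanded clonotypes (45, 41, 22, 95 and 21 cells), Tfh genes were higher in 5 of 5 libraries, with medians from 0.49 to 1.94, as were Th2 genes (0.25 to 1.31) and inhibitory receptors (0.03 to 1.25), and naive genes were lower in 5 of 5 (−2.21 to −0.49). The smallest inhibitory receptor median, 0.03, is close to no difference. With clonotypes of at least 3 cells that of week 0 went from 1.25 to 0, set by members at the floor. Maf had log2 ratios from 1.01 to 2.53 and Gzmk, a granzyme, from 1.18 to 3.03, at least 2-fold higher in all 5. Tigit (0.28 to 3.13), Lag3 (0.33 to 2.03), Cxcr5 (0.30 to 2.51), Cxcr3 (0.99 to 2.47) and Tox2 (0.19 to 2.72) were higher in 5 of 5. Pdcd1 was higher in 4 of 5, at 9.32, 0.684, 4.85, 2.98 and 4.30 times the level in single clonotypes. Ccr7 (−3.54 to −1.22) was at least 2-fold lower in all 5. Exhaustion-associated transcription factors were higher in 4 libraries and at 0 in the other, where members at the floor set the median, with a largest median of 1.20. In CD8 T-like cells, of which only 16, 16, 3, 32 and 13 were expanded, cytotoxic genes (0.42 to 3.26) and Th1 genes (0.77 to 3.28) were higher in 5 of 5, with Ccl5 (1.83 to 4.01), Gzmk (1.56 to 3.53) and Itgb1 (1.50 to 2.74) at least 2-fold higher each time.

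The BCR libraries were used to ask how antibody class and B cell clones differed. Class-switched heavy chains, those other than IgM and IgD, were found in 1.49% (1.16 to 1.88), 16.0% (14.9 to 17.2), 29.1% (27.3 to 31.0), 23.7% (22.4 to 24.99) and 35.2% (33.0 to 37.4) of cells with an assigned heavy chain class, from 4657, 4175, 2404, 4245 and 1927 cells with a heavy chain. IgG1, the class that Il4 favours in mice, was 0.086% (0.023 to 0.220) at week 0 and 10.8%, 20.6%, 20.9% and 21.1% later. At week 12 the largest clonotype made up 451 of the 889 barcodes with IgG1, and in B-like and plasma-like cells alone IgG1 was 0.103%, 10.13%, 18.7%, 10.97% and 17.4%. IgM was 80.7%, 68.0%, 54.8%, 53.2% and 48.5%. IgE heavy chains were in 1, 1, 14, 9 and 25 cells. With B-like and plasma-like cells of the RNA libraries alone, the switched share at weeks 6, 12 and 16 was 24.0%, 13.8% and 23.2%. In B-like cells alone it was 1.15%, 12.7%, 18.4%, 12.1% and 13.9%, and in plasma-like cells 27.8%, 64.5%, 47.9%, 52.6% and 62.8%. IgE was in 0 of 54 plasma-like cells at week 0, for which 3 counts would be 5.56% and the exact upper limit is 6.60%, and in 1, 11, 4 and 12 cells later. A heavy chain was found in 78.7%, 66.8%, 32.8%, 65.0% and 44.2% of B-like cells, so the shares of weeks 6 and 16 rest on a smaller part of the class.

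**Figure D4:**
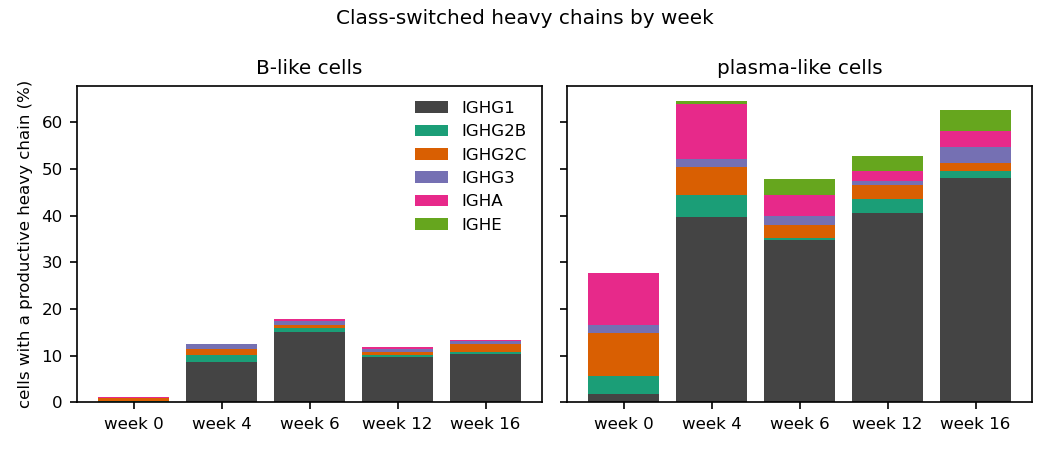
Share of cells with a productive heavy chain (percent, linear axis from 0) by class-switched constant gene and week, stacked, in B-like cells (left) and plasma-like cells (right), without error bars. IgG1 makes up 8.69% of B-like cells at week 4 and 15.1% at week 6, and 47.9% of plasma-like cells at week 16.

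Heavy chain clonotypes were more expanded in the infected libraries. Drawn to 1927 cells each, 2.18%, 6.51%, 18.1%, 13.5% and 16.3% of cells were in clonotypes of 2 or more cells, and the inverse Simpson index was 1879, 1077, 427, 85.1 and 151. The largest clonotypes held 5, 82, 77, 453 and 149 barcodes, and of those of weeks 4, 6, 12 and 16 only 82.9%, 46.8%, 9.49% and 3.36% were also in the RNA library, against 99.2%, 94.5%, 98.6% and 92.1% for all other clonotypes. With B-like and plasma-like cells of the RNA libraries alone, drawn to 1443 cells, the shares were 1.42%, 4.33%, 8.66%, 2.19% and 4.57% and the index was 1422, 1137, 1078, 1407 and 1237, so the low index of weeks 12 and 16 was not seen there. Among plasma-like cells 12.96%, 29.0%, 36.8%, 21.8% and 21.3% were in expanded clonotypes, and among B-like cells 3.84%, 7.07%, 5.49%, 4.39% and 2.21%. These shares, of 54, 169, 326, 133 and 267 plasma-like and 3830, 3464, 1439, 3141 and 1176 B-like cells, were not drawn to a common number. Their order by week may also follow the number of cells. The IgG3 share at week 16, 8.77% or 169 cells, was made up of the largest clonotype in 149 of them, and the IgG2b share at week 6, 3.79% or 91 cells, in 75.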

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

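The tests of free RNA, of fewer naive cells, of depth and of the largest heavy chain clonotype were chosen only after the results were seen, and those of library batch were planned.

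BCR barcodes that were not among the barcodes of the RNA library were more frequent after infection than in the uninfected control, where they made up 1.47% with an upper bound of 1.83%. No comparison of the RNA data uses these barcodes, and they stood out because their share lay above the control's interval in all 4 infected libraries. At week 4 they made up 2.28% (1.89 to 2.73), at week 6 10.7% (9.81 to 11.6), at week 12 10.2% (9.43 to 11.1) and at week 16 14.6% (13.3 to 15.9). Their heavy chains were class-switched in 5.26%, 52.1%, 61.1%, 94.1% and 86.9%, against 1.46%, 15.6%, 26.7%, 14.9% and 26.0% of the BCR barcodes that were in the RNA library. A single clonotype made up 41 of 170, 410 of 462 and 144 of 285 of the heavy chain barcodes outside at weeks 6, 12 and 16, and without the largest clonotype of each library the switched shares outside were 5.26%, 32.4%, 48.4%, 47.1% and 73.4%. The difference between these groups of barcodes was not tested between weeks, since each week has 1 library.

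The first pattern weighed was the gain of inhibitory receptor and Tfh genes in CD4 T-like cells of all 4 infected libraries. Free RNA from other cells was argued against, since such RNA would reach every class: over 44 pairs of gene and week, the smallest gain among B-like, CD8 T-like and neutrophil-like cells had a median of −0.0028 times that in CD4 T-like cells (−0.0108 to 0). A real fall in any of these classes also lowers the smallest gain, so the measure leans toward this outcome. For Pdcd1, Tigit and Lag3, few B-like cells had a UMI in any library, as given earlier. A loss of naive cells that lifts every non-naive gene alike was weighed by setting the Tfh list against the cytotoxic list. The Tfh median exceeded the cytotoxic median by at least 1.14 (0.85 to 1.58, at week 16), with differences of 1.33, 2.03 and 1.47 at weeks 4, 6 and 12. These lists did not rise alike, but this does not decide whether naive cell loss raised the Tfh genes. The cytotoxic list holds Klrd1, which was lower in all 4 infected libraries. A cluster led by Cxcr6 and Zbtb16 also held 5.49% of CD4 T-like cells without Treg-like cells at week 0 and 2.37%, 4.41%, 1.84% and 4.32% later. Library batch cannot be told apart from infection, since there was 1 RNA library per week. A change in which CD4 T cells were present, such as more Tfh cells, stays open beside a change within cells.

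The second pattern was the peak of type I interferon genes at week 4, seen in all 8 cell classes compared. Depth per cell was weighed by thinning each cell to 1000 UMIs, where the list median stayed above 0.5 in 8 of 8 classes (1.19 to 2.87). CPM are already scaled to the class total, so thinning mostly gives each cell the same weight, and this outcome was likely beforehand. It shows that the peak did not rest on the deepest cells alone, and draws no further conclusion about depth. Free RNA from 1 source was argued against, because 10 of the 11 genes took shares of the gain that differed at least 2-fold between classes with intervals apart. Library batch cannot be told apart from the week, with 1 RNA library per week. A response of the cells to infection stays open beside it.

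The third pattern was the largest heavy chain clonotype at week 12, an IgG1 sequence with IGHV8-5 in 453 barcodes. Expansion of intact cells was argued against as its source, because 9.49% (6.96 to 12.6) of its barcodes were in the RNA library, against 98.6% of the barcodes of other clonotypes. RNA of a few plasma cells caught in barcodes without a cell may be the source instead: 2 plasma-like cells carried the sequence, and a single barcode held 40.1% of its 7200 heavy chain UMIs. The expanded shares, class-switched shares and inverse Simpson index taken from all BCR barcodes at week 12 therefore count this sequence many times over, which is why values from B-like and plasma-like cells alone stand beside them. The largest clonotypes of weeks 4, 6 and 16 also lay outside the RNA library more than others did (82.9%, 46.8% and 3.36% of barcodes in it, against 99.2%, 94.5% and 92.1%). Of the 68 barcodes of the week 4 clonotype in the RNA library, 15 were plasma-like, 31 B-like and 16 not kept. Its top barcode held 6.46% of its UMIs. Those of weeks 6 and 16 had 0 and 0 plasma-like carriers and top barcodes with 3.75% and 2.24% of their UMIs, unlike that of week 12. Of the 36 barcodes of the week 6 clonotype in the RNA library, 14 were neutrophil-like, 3 B-like and 15 not kept. A neutrophil-like cluster with 41 of its 43 cells at week 6 had a BCR chain in 86.0% of cells and Slpi and Mzb1 among its leading genes. Whether its cells carry this clonotype was not examined. Plasma cell RNA caught with other cells thus stays open, as does the source in all 3 weeks.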

How the results depend on the processing

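The settings that leave out the CD4 T-like cluster c37, the largest at week 6, and that keep only BCR barcodes found in the RNA libraries were chosen after seeing the data, and the others were planned. No paired analysis was possible because each week had a single library and nothing links a mouse of one week to a mouse of another. Across 221 results, 935 of 1282 recomputed values stayed close, 306 moved and 41 changed sign. A value stayed close if it lay inside the counting interval of the reported value, and a change of sign was counted only where that interval left out 0. Of the 41, 31 used week 4 in place of week 0. Without that setting, 925 of 1177 values stayed close, 242 moved and 10 changed sign. Some lists in the report were not recomputed. By subject, 11 of 473 values for CD4 T-like cells changed sign, 8 of 114 for CD8 T-like and NK-like cells, 17 of 183 for B-like and plasma-like cells, 4 of 184 for myeloid cells and 1 of 195 for class shares. None of the 58 values for expanded against single clonotypes did. The 25 values for TCR clonality and 50 for BCR libraries are shares, which cannot change sign. Of these, 13 and 22 moved. Unless a reason is given, the cause was not tested. Counts limit rare genes most, and a mouse-to-mouse spread could not be had at any depth.

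Class shares are given as log2 ratios to week 0. With at least 500 genes and at most 5% mitochondrial UMIs, neutrophil-like ratios at weeks 4, 6, 12 and 16 were 0.87, 3.66, 1.92 and 3.39 in place of 0.58, 3.24, 1.53 and 2.996. Thinned before clustering, they were 0.91, 3.69, 1.95 and 3.38, and the CD4 T-like and Treg-like ratio at weeks 4, 6 and 12 was −0.84, −1.35 and −0.63 in place of −0.61, −1.20 and −0.50. That ratio was −0.29, −1.10, −0.16 and −1.35 with each library clustered by itself (main value −0.89 at week 16), −0.41, −1.43, −0.32 and −1.15 with cells gated by Cd4 and Cd8 UMIs, and −1.62 and −0.41 at weeks 6 and 12 without doublet removal. With a productive heavy chain in place of the cluster, B cell ratios were 0.009, −1.11, −0.08 and −0.70 in place of 0.20, −0.19, 0.16 and −0.15, so that of week 12 changed sign. Fewer B-like cells had a heavy chain in the infected libraries, which by construction lowers these ratios. For NK-like cells at week 16 no ratio could be had with each library clustered by itself, where 0 of 6531 barcodes were named so, and this case is not in the counts above. Macrophage-like shares at week 0 were 1.27% with the stricter filter and 1.29% thinned before clustering, in place of 2.70%.

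The inhibitory receptor median of CD4 T-like cells kept its sign in every setting run. Without Treg-like clusters it was 1.73, 1.78 and 1.71 at weeks 4, 12 and 16, without doublet removal 1.51 at week 6, and without c37 1.54 at week 6. At week 16 it was 1.73 thinned to 1000 UMIs, 1.08 gated by UMIs and 1.17 with no minimum count. Against week 4 it was 0.053, 0.18 and 0.17 at weeks 6, 12 and 16.

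With week 4 as the baseline, a gain that peaked at week 4 turns negative by construction. In CD4 T-like cells the type I interferon median of week 6 became −1.47, proliferation −0.61 and −0.79 at weeks 6 and 12, exhaustion-associated transcription factors −0.46 at week 16, Th2 −0.18 and −0.28 at weeks 6 and 16, Treg −0.38, −0.24 and −0.49 at weeks 6, 12 and 16, activation −0.38 at week 6 and naive genes 0.11 at week 12. In CD8 T-like cells naive genes became 0.005, 0.11 and 0.056, type I interferon −1.82 at week 6, and inhibitory receptors moved from 0.12 to −0.58 at week 6. In NK-like cells inhibitory receptors became −0.38 and −0.27 at weeks 6 and 12. In B-like cells the medians at weeks 6, 12 and 16 became −0.27, −0.17 and −0.87 for germinal centre genes, −0.24, −0.48 and −1.01 for proliferation and 0.10, 0.61 and 0.62 for follicular genes. Marginal zone genes became 0.10 and 0.046 at weeks 6 and 16, and type I interferon −2.43 at week 6. The interferon-gamma response at week 12 became −0.60 in monocyte-like and −0.26 in macrophage-like cells. Alternative activation in monocyte-like cells moved from 0.25, −0.29 and 0.29 to −1.01, −1.55 and −0.74.

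With TMM scaling, the CD8 T-like naive median of week 6 went from −0.13 to 0.037, the B-like marginal zone median of week 6 from −0.08 to 0.12 and the germinal centre median of week 6 from 2.38 to 2.58, shifts that follow from the factor applied to every gene. In plasma-like cells the same scaling took the secretory medians of weeks 12 and 16 from −0.48 and −0.58 to 0.14 and 0.27 and the proliferation median of week 6 from −0.40 to 0.011, which was 0.93 thinned to 1000 UMIs. Thinned to 1000 UMIs, germinal centre medians were 3.02, 2.60, 2.47 and 1.82, the CD8 T-like inhibitory median of week 12 went from 0.08 to 0.51, the NK-like type I interferon median of week 6 from −0.47 to 0.25, the monocyte-like alternative activation median of week 6 from 0.25 to 0.98, and the monocyte-like interferon-gamma medians of weeks 6 and 16 from −0.37 to 0.35 and from −0.25 to 0.30.

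For TCR clonality, the drawn expanded shares were 1.67%, 3.59%, 4.75% and 6.32% at weeks 0, 4, 12 and 16 with the beta chain alone, which by construction merges clonotypes. T-like cells of the RNA libraries gave 1.18% and 3.07% at weeks 4 and 6 in draws of 716 cells, draws of 500 cells 1.20%, 3.37%, 1.73% and 3.07% at weeks 4, 6, 12 and 16, and chains with at least 3 UMIs 0.974%, 1.56% and 2.33% at weeks 4, 12 and 16. For BCR clonality, heavy chains with at least 3 UMIs gave 1.36% at week 0, and B-like or plasma-like cells of the RNA libraries gave 1.42%, 4.33%, 8.66%, 2.19% and 4.57% in draws of 1443 cells, a smaller draw that by itself lowers the share. Cells other than plasma-like ones gave 5.33%, 14.3% and 14.6% at weeks 4, 6 and 16, and barcodes of the RNA libraries 5.43%, 12.4%, 3.68% and 7.31% in the infected weeks (draws of 1642 cells). The class-switched share at weeks 6, 12 and 16 was 24.0%, 13.8% and 23.2% in B-like or plasma-like cells and 26.7%, 14.9% and 26.0% in barcodes of the RNA libraries, and without plasma-like cells it was 13.9%, 26.1% and 30.6% at weeks 4, 6 and 16. With clonotypes of at least 3 cells, the inhibitory median of expanded CD4 T-like cells at week 0 went from 1.25 to 0, set by members at the floor.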

Other observations

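Innate-like T cells left a trace in the receptor data. The invariant TCR alpha chain of natural killer T cells, TRAV11 joined to TRAJ18, was found in 76, 19, 3, 12 and 8 barcodes at weeks 0, 4, 6, 12 and 16, or 2.15% (1.70 to 2.69), 0.834% (0.503 to 1.30), 0.291% (0.060 to 0.847), 0.461% (0.239 to 0.804) and 0.857% (0.370 to 1.68) of barcodes with a TCR alpha chain. UMIs of Zbtb16, the transcription factor of these cells, were in 40 of 65, 9 of 16, 3 of 3, 4 of 10 and 2 of 7 T-like cells with this chain, against 8 of 2968, 4 of 1900, 3 of 787, 1 of 2251 and 0 of 808 with another alpha chain and 2, 1, 1, 0 and 0 B-like cells. Thinned to 1000 UMIs, they were in 20 of 65, 3 of 16, 0 of 3, 0 of 10 and 0 of 7 with this chain and in 5 of 2954, 2 of 1887, 1 of 776, 0 of 2245 and 0 of 801 with another. Zbtb16 was also 22.5 CPM in CD4 T-like cells at week 0 and 4.04, 6.16, 3.46 and 3.12 CPM later. Zbtb16 (ENSMUSG00000066687) lies on chromosome 9 at 48654297 to 48836222. The alpha chain of mucosal-associated invariant T cells, TRAV1 joined to TRAJ33, was in 3, 2, 4, 0 and 0 barcodes, and for the counts of 0 the share of 3 counts would be 0.115% and 0.321% and the exact upper limits are 0.142% and 0.394%.

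Expanded clonotypes with at least 2 classed cells were made up of CD4 T-like cells alone in 18 of 26, 10 of 21, 6 of 9, 35 of 50 and 7 of 13 cases.

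Heavy chain clonotypes were rarely shared between libraries, with 24 of 15800 found in 2 or more libraries.

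The values of this part were chosen for mention only after the data had been seen, and no test was made on them.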
